A study of Mus musculus with 8 samples.

How the data were processed

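RNA-seq was read from 8 mouse libraries, 6 of embryonic brain and 2 of mouse embryonic stem cells (mESC). The brain libraries form 2 groups of 3. The NTD (neural tube defect) group came from dams on a low folate diet that received methotrexate, an antifolate drug, at 1.5 mg/kg on gestational day 7.5. The control group is labelled with normal saline, and the diet of its dams is not given in the labels, so diet and methotrexate are compared together. Embryos were taken in a window from day 9.5 to 10.5. The mESC libraries, 1 per group, came from cells of the Sv129 background kept without folic acid (FA0) or with 4 mg/L folic acid (FA4). Groups and replicate numbers follow the sample labels.

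Per the labels' protocols, ribosomal RNA was removed, libraries were made with a low input kit, and paired reads of 150 bp were sequenced. Per the submitters' processing notes, cutadapt 1.9.3, HISAT2 2.0.4, HTSeq 0.9.1 and edgeR were used with build mm10. The step that each tool served, the annotation and the strand setting are not given in the sources used here. The deposited brain table holds read counts per gene, per the file headers, for 14496 protein-coding genes. Each of them has at least 1 count in total. For mESC the authors deposited a table with estimated counts, FPKM values, a log2 ratio and p-values with an FDR. It lists 9217 genes in 23089 entries, once for each peak of a second assay that the labels do not name. The peak values were not used here. From the median ratio of deposited counts to FPKM over 2953 genes above 20 FPKM in both, the FA0 library had 1.334 times the depth of the FA4 library. Taken instead over genes with a minimum count in both libraries, the median was also 1.334. This second value was used for count ratios, since the totals of the listed genes cover part of each library. The authors' deposited log2 values equal the ratio of the FPKM columns with zeros replaced by 0.001.

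Brain counts were tested with edgeR 4.0.16 (quasi-likelihood F-test with robust dispersion, TMM scaling, filterByExpr), and p-values were adjusted by the Benjamini-Hochberg method over the 11626 genes kept. A gene was called at an adjusted p under 0.05, with no fold threshold unless stated. Standard errors (SE) were taken from the test statistic, and 95% intervals used its total degrees of freedom. Values per gene are CPM (counts scaled to library size) after TMM scaling. Where all libraries of a group held 0 counts, the fold is a lower bound against 3 counts per library in that group. With 1 to 3 counts in a group, the ratio is given with its exact binomial interval over the pooled counts. Such bounds and intervals cover counting error only and leave out the spread between libraries. Gene lists, 36 by name and 4 by symbol pattern, were fixed before the data were examined. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), again with an estimated correlation, and with fry. Adjusted p-values of lists cover the 37 lists tested. The labels do not say that replicates came from separate litters, so p-values measure the spread between these samples.

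In mESC no test across conditions was possible with 1 library per group. The log2 ratio of FA0 to FA4 was taken on the log2(FPKM + 1) scale, which understates changes of low genes, for the 6771 genes with a mean of at least 5 FPKM. Estimated counts were rounded to whole numbers for an exact binomial 95% interval of the count ratio, which covers counting error only. A list was placed by the percentile of its median among 10000 random lists of the same size matched on mean expression.

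Named genes followed a rule fixed in advance. For brain it took the 8 largest rises and 8 largest falls among called genes with non-overlapping groups and a mean of at least 1 log2 CPM, leaving out predicted genes, pseudogenes and small RNAs. It added 2 to 4 members of each list with the smallest p, and 11 genes named regardless of their values, 1 of which is not reported here. For mESC it took the 8 largest rises and falls at a mean of at least 5 FPKM, up to 3 members per list with the largest ratio at a mean of at least 1 FPKM, and the same 11 genes. Coordinates come from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, matched by gene identifier for 14420 of the brain genes.

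The alternatives were DESeq2 1.42.0, limma-voom, size factors in place of TMM, library totals alone, no filter and a filter of 5 CPM in 3 libraries. They also included the replicate number as a block, each library left out in turn, and removal of globin, mitochondrial and structural RNA genes. For mESC they were pseudocounts of 0.1 and 5, scaling by the median ratio, and minimums of 1 and 10 FPKM. Chosen after seeing the data were the removal of control library 1 together with NTD library 3, and count ratios in place of FPKM. Methods were tested on simulated data. Among 11111 simulated genes for the brain comparison, edgeR recovered 2.1% of 2-fold, 23.4% of 4-fold, 38.3% of 8-fold and 54.2% of 16-fold changes, with 7 false calls among 73. DESeq2 gave 88 false calls among 180 on the same genes, and limma-voom 1 among 56. The simulated counts were drawn with dispersions that edgeR estimated, which may favor edgeR. Camera called a shifted list and 0 of 20 null lists. The simulated genes were drawn independently, so this check could not show false list calls that come from correlated genes. For mESC, 96% of simulated count-ratio intervals held the true ratio over 8329 genes. R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used.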

Results

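Embryonic brain RNA was profiled in 3 NTD and 3 control libraries, and mESC RNA in 1 FA0 and 1 FA4 library. The brain comparison asks which genes differ in embryos of dams under folate shortage and methotrexate, and the mESC comparison asks the same for cells without folic acid. Brain libraries held 22333991, 26238026 and 18959473 counts in controls 1 to 3 and 26437034, 26788304 and 17335564 in NTD 1 to 3. The listed mESC genes held 3901965 counts in FA4 and 5247130 in FA0. Across genes, the log2 CPM of control libraries 2 and 3 correlated at 0.91, while control library 1 correlated with them at 0.775 and 0.76. The NTD libraries correlated with each other at 0.718 to 0.749, and libraries of different groups at 0.595 to 0.704. Genes are not independent replicates in these correlations. On the second principal component (23.3% of the variance), control library 1 and NTD library 3 lay at 126.68 and 112.95, apart from the other 4 libraries (-75.53 to -38.76). Of 6440 genes with a mean of at least 500 counts, 99 had 3 counts or fewer in control library 1, 35 in control library 2, 35 in NTD library 3 and 8 to 18 in each of the others.

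In NTD brain libraries, genes of trophoblast (the outer lineage of the placenta) and of yolk sac endoderm were higher, and genes of differentiating neurons were lower. Prl3d2, a placental lactogen gene of giant trophoblast cells, rose from 0.0957 ± 0.0916 to 1200 ± 343 CPM (mean ± SD, n = 3 per group, adjusted p = 3.7e-05). Dcx, which encodes a microtubule protein of young neurons, fell from 436 ± 53.1 to 45.8 ± 8.67 CPM (log2 fold change -3.25 ± 0.25 SE, adjusted p = 0.000613). With edgeR's quasi-likelihood test, 220 genes were higher and 116 lower in NTD at an adjusted p under 0.05. With a change of at least 2-fold, 213 were higher and 114 lower. In all 336 called genes the 3 NTD values lay on one side of the 3 control values, which 24.5% of all tested genes showed and 10% would show by chance. Among the 220 higher genes, 95 had a control mean under 1 CPM. The counts depended on single libraries. They were 33 higher and 17 lower without NTD library 1, 108 and 73 without NTD library 2, 79 and 74 without NTD library 3, 90 and 50 without control library 2, and 148 and 49 without control library 3. Of 50 called genes that were followed through these fits, 15 kept an adjusted p under 0.05 whichever library was left out, and none changed sign. In every alternative that was fixed before the data were examined and that tested the gene, 13 kept it. They were Prl3d2, Apoa1, Ttr, Dcx, Ina, Elavl3, Stmn2, Fabp7, Slc2a3, Krt18, Cldn6, Hand1 and Hbb-bt. Hbb-bt was not tested in the fit that removed globin genes. Left out together, control library 1 and NTD library 3 gave 250 higher and 111 lower genes, a setting chosen after seeing the data.

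Of the 9 trophoblast markers tested, 7 were higher in NTD, and 9 were higher when adjusted over the list alone (camera adjusted p = 2.67e-13, and adjusted p = 0.0234 with an estimated correlation). Tpbpa, a marker of spongiotrophoblast, held 0 counts in the controls and 35.1 ± 2.9 CPM in NTD, at least 267-fold higher (adjusted p = 0.00423). Prl3d3 and Prl8a9, both of the placental prolactin family, were at least 245-fold and at least 186-fold higher, from 0 counts in controls. Rhox9, a homeobox gene of placenta and gonad, rose from 0.186 ± 0.291 to 78.4 ± 16.6 CPM (adjusted p = 0.00568). Prl3d1 held 1 count over the control libraries and 2080 over the NTD libraries, a ratio of 2130 with a 95% interval from 382 to 84300. Prl3d1, Prl3d2 and Prl3d3 are near-identical copies, so the reads of each are uncertain. The control level of the yolk sac list was 629 ± 481 CPM summed over its members, against 16300 ± 2085 CPM in NTD.

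Of the 15 yolk sac and visceral endoderm markers, 7 were higher, and 12 were higher when adjusted over the list alone (camera adjusted p = 4.59e-13, but adjusted p = 0.105 with an estimated correlation). Apoa1, an apolipoprotein gene, rose from 4.44 ± 3.59 to 585 ± 58.2 CPM (adjusted p = 0.0014). Apom rose from 0.57 ± 0.554 to 108 ± 48.6 CPM, and Amn, whose product takes up vitamin B12 complexes with cubilin, from 0.221 ± 0.352 to 111 ± 21.6 CPM. Ttr, a carrier of thyroid hormone and retinol, rose from 275 ± 77.8 to 1790 ± 612 CPM (adjusted p = 0.00258). Outside these lists, Muc13, Tbx5, Hoxc10 and Slc23a3 were among the 8 largest rises. They held 0 counts in controls and were at least 172-fold, 144-fold, 138-fold and 126-fold higher. Of the 16 surface ectoderm and epithelium markers, 6 were higher and 1, Krt5, was lower. When adjusted over the list alone, 7 were higher and 3 lower. The log2 changes of the list had a median of 1.118 and a mean of 0.012, and camera did not call the list (adjusted p = 0.104). It was called with the stricter expression filter (adjusted p = 2.77e-05), with fry (0.00725) and without control library 1 and NTD library 3 together (0.0339). Over all settings its adjusted p ran from 2.77e-05 to 0.288. Krt18, a keratin of simple epithelia, rose from 9.15 ± 1.37 to 248 ± 22.9 CPM (adjusted p = 0.000106), and Cldn6, a tight junction gene, from 39.1 ± 21.9 to 729 ± 68.5 CPM.

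**Figure D1:**
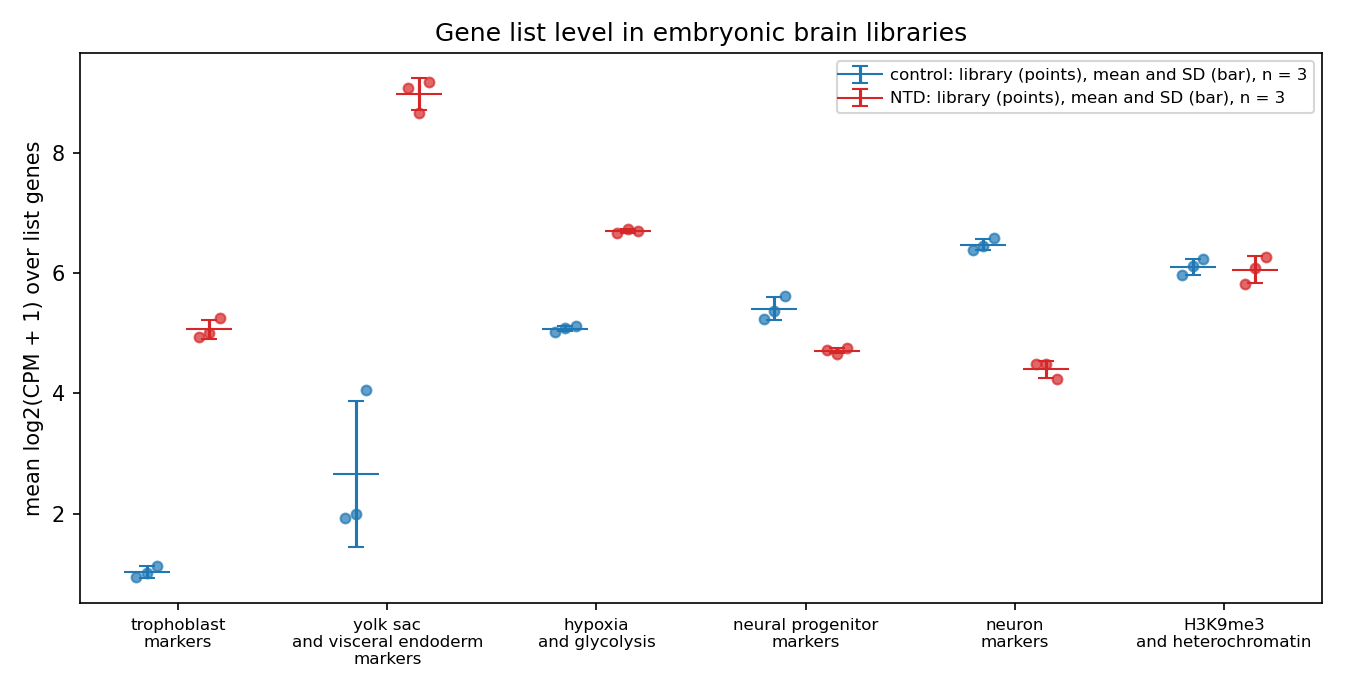
Mean log2(CPM + 1) over the tested genes of 6 lists, for each of the 3 control and 3 NTD brain libraries (points), with the group mean and SD (bars). Neuron markers sit at 6.47 in controls and 4.4 in NTD, and yolk sac markers at 2.66 and 8.97, while heterochromatin genes sit at 6.1 and 6.05.

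Of the 24 neuron markers, 13 were lower in NTD and 0 higher, and 16 were lower when adjusted over the list alone. The trophoblast and yolk sac levels given above differed between the same libraries. The neuron list median was -2.33 on the log2 scale (camera adjusted p = 4.59e-13, and adjusted p = 0.0234 with an estimated correlation). Beside Dcx, Ina, a neuronal intermediate filament gene, fell from 545 ± 57.7 to 71.6 ± 12.5 CPM (adjusted p = 0.000613). Elavl3 fell from 447 ± 77.7 to 73.8 ± 15.3 CPM and Stmn2 from 385 ± 53.9 to 73.8 ± 13.5 CPM. Among the 8 largest falls, Gad2, an enzyme of GABA synthesis, held 17.6 ± 5.69 CPM in controls and 0 counts in NTD, at least 128-fold lower (adjusted p = 0.0325). Trim67 and Tmem145 also held 0 counts in NTD and were at least 133-fold and 132-fold lower. Rab33a held 2174 counts over the controls and 2 over the NTD libraries, a ratio of NTD to control of 0.000943 with a 95% interval from 0.000114 to 0.00341. For Pnma2, Krt5 and Kcnj8, with 1 count each in NTD, the ratios were 0.000821 (interval 2.08e-05 to 0.00458), 0.000841 (2.13e-05 to 0.00469) and 0.001 (2.54e-05 to 0.0056). Lamp5 fell from 44.3 ± 24.3 to 0.0802 ± 0.139 CPM (adjusted p = 0.0124).

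Of the 21 neural progenitor markers, 3 were lower and 6 were lower when adjusted over the list alone, with a list median of -0.83 (camera adjusted p = 0.00503, but adjusted p = 0.111 with an estimated correlation). Fabp7 fell from 236 ± 27.1 to 43.6 ± 2.42 CPM (adjusted p = 0.00175). Zic1 fell from 213 ± 43.2 to 64.1 ± 20.5 CPM, and Hes5, a Notch target, from 240 ± 41.4 to 83.5 ± 23.3 CPM. Among 34 genes whose mouse mutants have neural tube defects, 2 were lower and the list was not called (camera adjusted p = 0.252). Scrib, a planar polarity gene on chromosome 15 from 76047158 to 76069784, fell from 241 ± 23.5 to 87.1 ± 19 CPM (adjusted p = 0.0174), a call lost in 5 of the 6 fits that left out a library (adjusted p up to 0.0658). Pax3, a dorsal neural tube regulator on chromosome 1 from 78101267 to 78197134, fell from 137 ± 17.1 to 51.3 ± 2.7 CPM (log2 fold change -1.42 ± 0.27 SE, adjusted p = 0.0271). Leaving out any one library ended the call of Pax3, with adjusted p between 0.0623 and 0.098. Vangl2 was at 93.8 ± 19.4 and 65.6 ± 20.9 CPM (adjusted p = 0.604).

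Several glycolytic genes were higher in NTD, as were the one-carbon genes Mthfd2 and Mthfd1, although the call of Mthfd1 depended on each library. Of 20 hypoxia and glycolysis genes, 8 were higher and 14 were higher when adjusted over the list alone (camera adjusted p = 2.11e-08, and adjusted p = 0.036 with an estimated correlation). The NTD libraries with these higher levels were also those with high yolk sac and trophoblast levels. Slc2a3 and Slc2a1, which encode glucose transporters, rose from 103 ± 2.16 to 1500 ± 318 CPM and from 298 ± 43.8 to 1710 ± 725 CPM. Pfkl, the liver form of phosphofructokinase, rose from 49.7 ± 13.5 to 190 ± 30 CPM (adjusted p = 0.0105). Of 25 folate and one-carbon genes, 2 were higher and 9 were higher when adjusted over the list alone (camera adjusted p = 0.000728, but adjusted p = 0.111 with an estimated correlation). Mthfd2, a mitochondrial folate enzyme, rose from 50.8 ± 4.21 to 180 ± 36.9 CPM (adjusted p = 0.00955), and Mthfd1 from 78.4 ± 19 to 201 ± 28.2 CPM (adjusted p = 0.0332). Leaving out any one library ended the call of Mthfd1. Tyms, which encodes thymidylate synthase, was at 5.95 ± 6.47 and 1.21 ± 1.5 CPM (adjusted p = 0.757). Folr1, a folate receptor gene, was at 2.12 ± 1.99 CPM in controls and 41.5 ± 21 CPM in NTD and was not called (adjusted p = 0.161). Of 17 amino acid and integrated stress response genes, 3 were higher (camera adjusted p = 0.000112, but adjusted p = 0.0753 with an estimated correlation). Psat1 and Psph, enzymes of serine synthesis, rose from 106 ± 11.1 to 438 ± 185 CPM and from 79 ± 18.4 to 229 ± 34.2 CPM.

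Among lists of position, lineage and imprinting, several also moved between the libraries that differed in trophoblast and yolk sac level. Of 11 trunk Hox genes tested, 4 were higher (camera adjusted p = 1.92e-08, but adjusted p = 0.0718 with an estimated correlation). The expression filter kept these 11 of 19 measured, and genes low in controls pass it mainly when high in NTD. Of all tested genes under 1 CPM in controls, 48.8% had all NTD values above, against 10.4% of the others. The list test therefore leans toward a rise. Hoxa9 rose from 0.118 ± 0.107 to 48.1 ± 26.9 CPM, and Hoxd10, with 1 count over the controls and 1127 over NTD, had a ratio of 1160 with a 95% interval from 207 to 45700. Of 12 hindbrain Hox genes 0 were called, although camera placed the list lower (adjusted p = 0.027, but adjusted p = 0.178 with an estimated correlation). Of 17 imprinted genes, 3 were higher and 1 lower (camera adjusted p = 0.0204, but adjusted p = 0.154 with an estimated correlation). Phlda2 rose from 0.83 ± 1.11 to 343 ± 29.5 CPM and Peg10 from 284 ± 63.3 to 770 ± 291 CPM. Nnat, a neuronal gene, fell from 1780 ± 300 to 700 ± 108 CPM. Of 9 early lineage markers 2 were higher (camera adjusted p = 0.0222, but adjusted p = 0.296 with an estimated correlation). The filter kept these 9 of 13 measured, so this list test may lean toward a rise in the same way as that of trunk Hox genes. Hand1 rose from 1.18 ± 1.07 to 163 ± 39.5 CPM and Gata4 from 0.21 ± 0.275 to 48.3 ± 7.12 CPM. Of 77 cytosolic ribosomal protein genes 4 were higher, with a list median of 0.51 (camera adjusted p = 1.98e-06, but adjusted p = 0.363 with an estimated correlation). Rps3 rose from 1010 ± 166 to 1900 ± 92.7 CPM. Of 16 erythroid genes 1 was lower, and the list was not called (camera adjusted p = 0.222). That gene, Hbb-bt, which shares sequence with Hbb-bs, fell from 1030 ± 261 to 60.6 ± 27.4 CPM. Macrophage markers were placed lower by camera with 0 of 10 genes called (adjusted p = 0.0111, but adjusted p = 0.149 with an estimated correlation), as were midbrain genes with 0 of 9 (adjusted p = 0.027, but adjusted p = 0.205 with an estimated correlation). Single libraries decided some of these list calls. The hindbrain Hox call was lost without control library 1 (adjusted p = 0.188) or NTD library 1, 2 or 3 (0.0543, 0.0797 and 0.0551), and the early lineage call without the same libraries (0.399, 0.437, 0.243 and 0.289). The midbrain call was lost without control library 1 or NTD library 1 or 2 (0.0504, 0.0979 and 0.0529), the macrophage call without control library 1 or NTD library 3 (0.0504 and 0.128), and the imprinted call without NTD library 1 (0.0543).

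The series title names Alkbh1, a demethylase gene on chromosome 12 from 87425840 to 87444017, together with H3K9me3 heterochromatin. Alkbh1 was at 46.3 ± 16.5 CPM in controls and 49.5 ± 22 CPM in NTD, a log2 fold change of 0.09 ± 0.48 SE with a 95% interval from -0.98 to 1.17 (adjusted p = 0.968). Its direction turned when single libraries were left out. Of 24 H3K9me3 and heterochromatin genes 0 were called (camera adjusted p = 0.963), and of 15 AlkB family and N6-adenine methylation genes 0 were called (camera adjusted p = 0.652). Fry, which does not compare a list with other genes, placed the AlkB list higher (adjusted p = 0.0315), and its adjusted p with camera ran from 0.3 to 0.879. Suv39h1, a histone H3K9 methyltransferase gene, was at 125 ± 26.1 and 155 ± 10.3 CPM (adjusted p = 0.7). Setdb1, of the same enzyme class, was at 35.2 ± 19.8 and 11.4 ± 9.25 CPM (adjusted p = 0.416). Trim28 was at 600 ± 6.92 and 566 ± 69.1 CPM (adjusted p = 0.92), and Cbx5 at 226 ± 53 and 265 ± 20 CPM (adjusted p = 0.776). Alkbh5, an RNA demethylase gene, was at 138 ± 11.6 and 247 ± 29.7 CPM (adjusted p = 0.0846). Of 23 p53 target genes 0 were called (camera adjusted p = 0.963), and Cdkn1a was at 23.1 ± 8.51 and 32.7 ± 8.51 CPM (adjusted p = 0.794).

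The remaining lists were not called by camera with all libraries and the standard filter. The Zfp-numbered genes were placed lower with the stricter filter (adjusted p = 0.0438). Without control library 1 and NTD library 3 together, replication histones were placed lower (adjusted p = 0.0278) and muscle and heart genes higher (adjusted p just under 0.05). With all libraries and an estimated correlation, camera gave these 3 lists adjusted p-values of 0.407, 0.963 and 0.458. Fry pointed lower for muscle and heart genes (adjusted p = 0.0659). Of 20 purine and pyrimidine synthesis genes 1 was higher, Ppat, the first enzyme of purine synthesis (adjusted p = 0.0355). One call each was made among 13 endothelial, 16 extracellular matrix, 24 mitosis and 12 muscle and heart genes, namely Flt1, Fn1, Hmmr and Myl7, all higher. Boc, a co-receptor of Sonic hedgehog, was lower among 11 genes of that pathway, and Hist3h2a was lower among 17 replication histones. No gene was called among 233 Zfp-numbered zinc finger genes, 29 DNA replication genes, 16 canonical Wnt genes, 16 mesenchyme and neural crest markers, 17 cholesterol synthesis genes or 13 retinoic acid pathway genes. The same held for 12 forebrain, 7 somite, 5 naive pluripotency and 5 glia genes. Over all genes tested, 1748 had an unadjusted p under 0.05. With 4 tested members each, germline and mitochondrially encoded genes were too few for the list test. No mitochondrially encoded gene was called, but the summed level of 5 of them was 5756 ± 189 CPM in controls and 3762 ± 539 CPM in NTD. The cause of this difference was not tested.

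**Figure D2:**
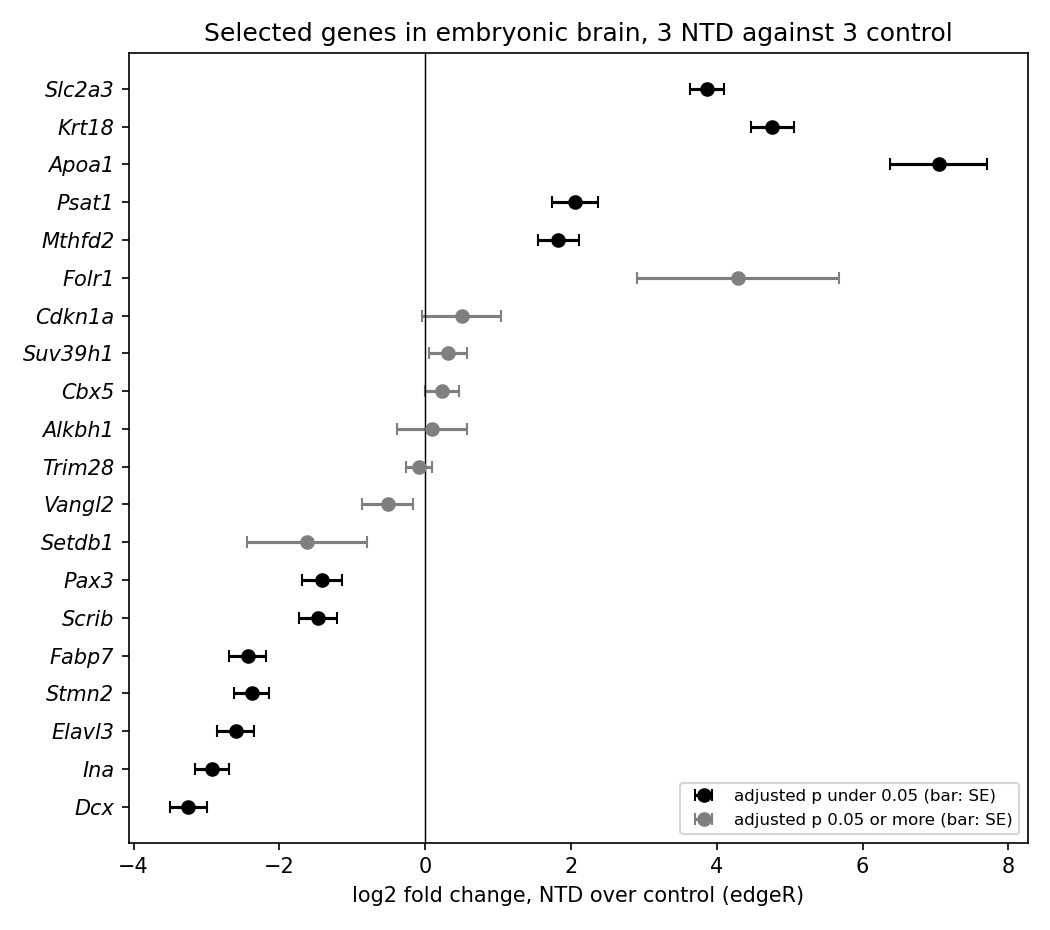
Log2 fold change of NTD over control (x axis, edgeR, bars are SE) for 20 genes, 3 libraries per group. Black points have an adjusted p under 0.05 and gray points do not. Dcx lies at -3.25 and Slc2a3 at 3.87, while Alkbh1 lies at 0.09.

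In mESC the 2 libraries differed little for most of the listed genes. The hypoxia, p53 target and pluripotency lists lay at the edges of what random lists gave. Only genes with a peak of the second assay are listed, so the mESC counts and percentiles do not cover other genes. Ddit3, a transcription factor of the integrated stress response, was at 13.24 FPKM in FA4 and 35.62 FPKM in FA0 (log2 ratio 1.36, count ratio 2.8 with a 95% interval from 2.1 to 3.78). Folr1 was lower, at 83.17 and 50.25 FPKM (count ratio 0.625, interval 0.528 to 0.74). With 1 library per group, these differences have no replicate check and carry no p-value. Of 6771 genes, 43 were at least 2-fold higher in FA0 and 41 at least 2-fold lower on the log2(FPKM + 1) scale. From the counts, 21 of the 43 were also at least 2-fold higher and 22 of the 41 at least 2-fold lower. The SD of the log2 ratios over genes was 0.32. In the authors' deposited table, 1773 genes have an FDR under 0.05, 941 of them higher in FA0, which compares those 2 libraries and not the conditions.

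The largest falls were Rap1gap (12 to 0.53 FPKM), Xrcc2 (10.81 to 0.67), Slc15a4 (82.39 to 12.91), Herc3 (32.64 to 6.63), Plekhm3 (8.87 to 1.44), Plcxd1 (9.74 to 2.26), Zfp101 (25.46 to 7.05) and Vcan (11.37 to 2.87). The largest rises were Bcl9 (2.33 to 11.03 FPKM), Phc2 (1.85 to 9.14), Erlec1 (3.08 to 11.7), Trappc9 (3.79 to 12.93), Crtac1 (3.55 to 11.96), Zfp623 (3.93 to 12.59), Ano9 (2.83 to 9.08) and Utp25 (3.17 to 9.83). Counts did not always move with FPKM. Among these, 6 of the 8 falls had a count ratio interval below 1 and 6 of the 8 rises had one above 1. A count ratio of 2-fold or more was reached by 3 of the 8 falls and 4 of the 8 rises. The count ratio of Slc15a4 was 0.722 (interval 0.594 to 0.877), that of Herc3 1.03 (interval 0.801 to 1.32) and that of Rap1gap 0.0465 (interval 0.0208 to 0.0908).

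Among the 19 lists placed, the median log2 ratio of 13 hypoxia and glycolysis genes was -0.21, at percentile 0.5 of random matched lists. Of its members 11 were lower, or 9 from count ratios. Slc2a1 was at 104.42 FPKM in FA4 and 81.54 in FA0, and Eno1 at 501.6 and 356.48. The median of 13 p53 targets was -0.25, at percentile 0.7, with Pmaip1 at 7.5 and 3.61 FPKM. The 18 amino acid and integrated stress response genes had a median of 0.1, at percentile 97, and Trib3 was at 28.8 and 45.32 FPKM. The 17 naive pluripotency genes had a median of 0.14, at percentile 99.1. Zfp42 was at 304.97 and 434.27 FPKM and Tfcp2l1 at 84.8 and 126.22, while Lefty2 was at 19.46 and 9.78. The 21 replication histones had a median of -0.17 (percentile 0.2) and the 48 cytosolic ribosomal protein genes one of 0.06 (percentile 99.8). The 5 surface ectoderm and epithelium markers had a median of -0.245 (percentile 2.5, or 0.3 from count ratios), with all 5 lower. The 25 genes of neural tube defect mutants had a median of -0.18 (percentile 0.2), with Zic2 at 17.41 and 7.73 FPKM and Vangl2 at 4.81 and 12.32. From count ratios in place of FPKM, that list was at percentile 11.4.

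Alkbh1 was at 46.54 FPKM in FA4 and 42.5 FPKM in FA0 (log2 ratio -0.13). Its count ratio was lower, at 0.801 (interval 0.713 to 0.9), and the ratio of its FPKM values lay above this interval. The 9 AlkB family genes lay at percentile 21.9 and the 25 H3K9me3 and heterochromatin genes at percentile 30.7, or 12.2 from count ratios. Atf7ip, a partner of Setdb1, was at 54.13 and 16.66 FPKM, with a count ratio of 0.834 (interval 0.732 to 0.95). Setdb1 was at 25.66 and 34.02 FPKM (count ratio 1.32, interval 1.2 to 1.46), Trim28 at 837.32 and 811.93, and Cbx5 at 116.44 and 101.78. The 19 folate and one-carbon genes lay at percentile 53.2, or 36.5 from count ratios. Suv39h1, Tyms, Cdkn1a and Pax3 were not analysed here in mESC.

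**Figure D3:**
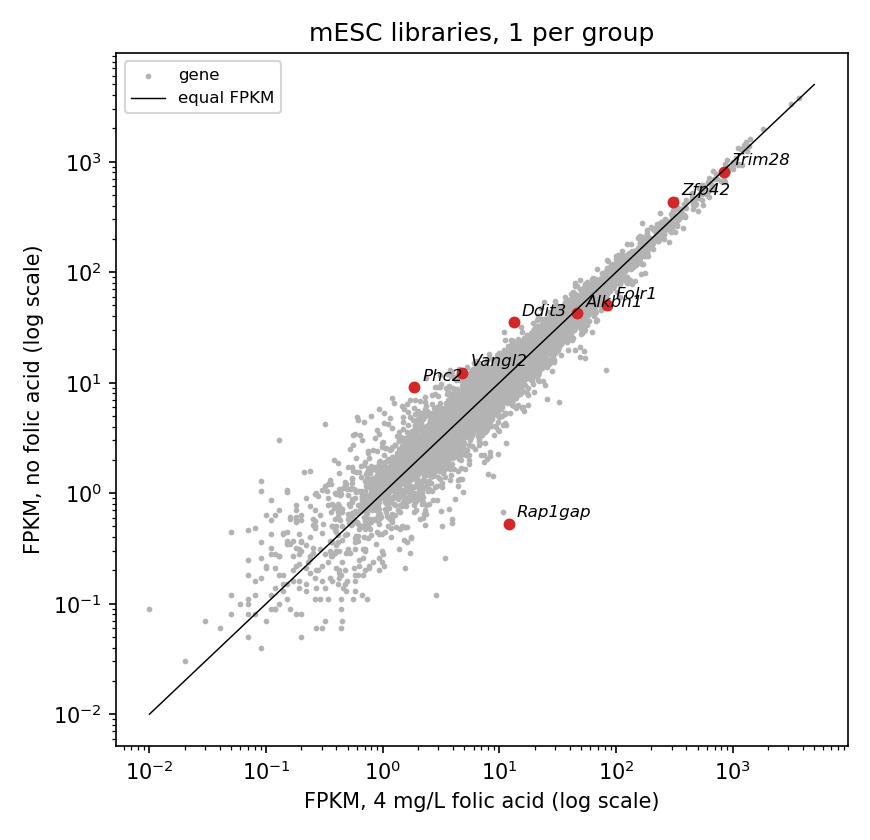
FPKM of each gene in the FA4 library (x axis, log scale) and in the FA0 library (y axis, log scale), 1 library per group. The line marks equal values, and Alkbh1 lies close to it at 46.54 and 42.5 FPKM while Rap1gap lies below it at 12 and 0.53.

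The brain and mESC comparisons were set side by side as models of folate shortage. Over 5804 genes, all from the listed mESC genes, the log2 changes correlated at a Pearson r of -0.027 and a Spearman rho of -0.033. Genes are not replicates in these correlations. Of 81 genes higher in NTD brain, 34 were also higher in FA0, and of 29 lower genes, 14 were also lower. Among all shared genes, 49.9% were higher in FA0. Hypoxia and glycolysis genes, higher in NTD brain libraries, had a median below 0 in FA0, and the difference between the comparisons was not tested. The summed yolk sac list was at 629 CPM in control and 16300 CPM in NTD libraries, so the rise cannot be placed in brain tissue. The mESC comparison has no replicates, and the biological coefficient of variation in brain was 0.94. A correlation near 0 therefore cannot tell whether the responses to folate shortage differ.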

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

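The removal of control library 1 with NTD library 3, and count ratios for mESC, were chosen after seeing the data. All 336 called brain genes kept their sign in every fit that tested them. DESeq2 called 609 higher and 427 lower genes (544 and 397 at 2-fold), with 335 of the 336 among them, but it gave 88 false calls of 180 on simulated data. Those data were drawn with edgeR's dispersions, so they do not settle how many of its calls in the real libraries are false. Limma-voom called 138 higher genes at 2-fold. Whether the replicate numbers pair the libraries could not be told. Same-numbered libraries had correlations of deviations of -0.021, 0.093 and 0.031. Control libraries 2 and 3 correlated best with the NTD library of the same number, while control library 1 correlated best with NTD library 3 (0.041). All these values are too near 0 to decide. With the replicate block the counts were 132 higher and 73 lower (130 and 73 at 2-fold), the block leaves fewer degrees of freedom, and 14 lists were called as without it. Leaving out single libraries gave 33 to 225 higher and 17 to 78 lower genes (33 to 225 and 17 to 77 at 2-fold). The lowest counts came without NTD library 1, and the cause was not tested. Of the higher and lower calls, 65.5% were higher with TMM and 59.5% with library totals alone, which moved the median of all genes to -0.11 from -0.015. With an estimated correlation 3 of the 14 lists remained, those of trophoblast, neuron and hypoxia genes. Fry called 19 lists, 13 of them shared, without the ribosomal proteins (adjusted p = 0.0658) and with AlkB, DNA replication, endothelial, extracellular matrix, naive pluripotency (median -0.26, yet placed higher) and epithelium lists. The stricter filter called 16, with epithelium and Zfp-numbered genes added. Leaving out single libraries gave 10 to 14 lists, losing hindbrain Hox, early lineage, midbrain, macrophage or imprinted lists and adding none. Leaving out control library 1 and NTD library 3 gave 13, of which 10 were shared, without the first 4 of these and with epithelium, muscle and heart, and replication histone lists. Alkbh1, not called in any fit, had a log2 change of 0 with library totals and -0.27 to 0.43 when single libraries were left out (adjusted p from 0.763 to 1 over all settings). The mESC counts of 2-fold changes were 7 higher and 15 lower with a pseudocount of 5, 95 and 82 at a minimum of 1 FPKM, and 12 and 22 at a minimum of 10 FPKM. The minimums changed the number of genes from 6771 to 8560 and 5126, while the pseudocount kept the 6771 genes and lowered the SD of their log2 ratios from 0.32 to 0.25. Count ratios (pseudocount 1) gave 38 higher and 32 lower, and of the 43 and 41 found with FPKM, 21 and 22 had a count ratio of 2-fold or more in that direction without a pseudocount. The correlation of brain and mESC changes lay between -0.036 and -0.017 in all settings. Over the single genes reported besides Alkbh1, brain and mESC together, 846 values under other settings were kept, 166 lost the call, 3 gained it and 19 moved. For brain, kept means the same direction and side of the threshold. For mESC, which has no test, kept means a shift within counting error, and the 19 moved beyond it. Pseudocounts cannot turn the sign of an mESC ratio and minimums leave its value unchanged, so part of the 846 was fixed in advance. The normalized-value alternatives for brain were not run, since the table holds counts. The depth of the brain libraries put 3 counts at 0.11 to 0.18 CPM, and genes of high mean count also fell to 3 counts or fewer in single libraries, up to 99 in control library 1, so depth is not the only limit on folds of genes at 0, and the biological coefficient of variation was 0.94.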

Other observations

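The ontology term tests, the tests of depth, dilution and stage, and the split of the further markers by control level were chosen after the results were seen, and the test of further markers and the splits before. Further gene groups were examined with the ontology terms of the deposited brain table. Of 518 terms, camera called 21 higher and 17 lower in NTD, and 0 with an estimated correlation. Among 38 genes that restrain peptidases, 7 were higher, Serpina1c, Ambp and Itih3 among them (adjusted p = 6.38e-06, but adjusted p = 0.596 with an estimated correlation). Among 70 axon guidance genes, 7 were lower, Robo3, L1cam and Nfasc among them (adjusted p = 0.00103, but adjusted p = 0.549 with an estimated correlation). Robo3, a receptor of crossing axons, fell from 197 ± 12 to 16.1 ± 6.73 CPM. Of 45 microtubule movement genes 4 were lower, the kinesin genes Kif5c, Kif1b, Klc1 and Kif3c (adjusted p = 0.0258, but adjusted p = 0.549 with an estimated correlation). Singled out after their values were seen, the metallothionein genes Mt1 and Mt2, similar in sequence, rose from 93.3 ± 27.8 to 794 ± 130 CPM and from 73.2 ± 7.74 to 1106 ± 233 CPM. Afp, the major secreted protein gene of yolk sac endoderm, was at 0, 12.49 and 40.4 CPM in the controls and 7046, 7735 and 7750 CPM in NTD, yet its adjusted p was 0.106.

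Trophoblast and yolk sac genes were higher in NTD libraries, with median log2 changes of 8.06 over all 9 trophoblast markers and 6.50 over all 15 yolk sac markers, and of 243-fold over the 14 called ones alone (bounds used for genes at 0 in controls), although the yolk sac list had an adjusted p = 0.105 with an estimated correlation. The ratio of mean library totals, NTD over control, was 1.04. These totals were known when the depth test was set and CPM values are scaled to library size. Its outcome was thus fixed, and no support is drawn from it. In 2 further marker sets with none of the first markers, 84.2% of 38 tested genes had all NTD values above all control values, against 12.4% of all tested genes, but genes under 1 CPM in controls pass the filter mainly when high in NTD, and 48.8% of these lay above. Among the 19 further markers with at least 1 CPM in controls the share was 73.7%, against 10.4% of all such genes, and over all 44 in the table with no filter it was 72.7%, which is consistent with placenta or yolk sac tissue in the NTD libraries as a candidate explanation. A change of gene activity within embryonic tissue under the treatment stays open, as does how the tissue was dissected, which the labels do not describe.

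Neuron genes were lower in NTD libraries, with a median log2 change of -2.33. If other tissue only diluted the brain, progenitor genes would fall as far. The gap between groups in neuron minus neural tube progenitor level was 1.04 on the log2 scale, above the summed SDs of 0.51. Neuron genes thus fell further than progenitor genes in these libraries. The test was set after the list medians of -2.33 for neuron and -0.83 for neural progenitor markers were seen, so a gap was foreseeable. Other tissue may also carry progenitor genes. No conclusion about dilution alone is drawn from this test. A younger stage of the NTD embryos, which the submitters describe as smaller and delayed, may lower neuron genes too, and the ratio of Hbb-bh1 to Hbb-y, which falls as embryonic red cells mature, was above all controls in 2 of 3 NTD libraries (1.36 and 1.57). The other, NTD library 3, was at 0.977, against 0.99 in control library 1 and 0.422 and 0.455 in control libraries 2 and 3. The test as first set counted any overlap against a younger stage. That reading was changed after the value was seen, because the overlap is far smaller than the SDs of 0.3 and 0.319. Stage therefore cannot be told apart from treatment.

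Over the 10 ways to split the 6 brain libraries into 3 and 3, the real split called 336 genes and the highest other split 3. At 2-fold the values were 327 and 3, and for lists 14 and 4. The real split alone (1 of 10) reached its counts, and 10 splits are too few for a share under 0.05.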
